A study of Homo sapiens with 40 samples.

How the data were processed

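The series holds 40 libraries of guide RNA (gRNA) sequences, amplified from the genomic DNA of cells that had been sorted by the level of a surface protein. They come from 8 screens, each with its own deposited table and with a high and a low bin, which makes 16 groups. CRISPRi libraries carried a nuclease-dead Staphylococcus aureus Cas9 fused to the KRAB repressor domain (dSaCas9-KRAB, as the tiling labels give it), CRISPRa libraries an activating fusion, and knockout libraries a cutting Cas9. Each table gives read counts per gRNA as deposited by the authors, not normalized. Per the labels' protocols, genomic DNA was amplified over 25 PCR cycles, without a stated molecular identifier. Per the submitters' processing notes, Bowtie, Bowtie2, DESeq2 and the human genome build hg38 were used; their versions and their roles are not given in the sources used here, and neither are the read filters or the mismatches allowed. PCR copies of the same molecule are therefore counted separately, and intervals from counts cover counting error only. The time label, 9 for the CD2, B2M and knockout screens and 10 for the others, has no unit in the labels and entered no test.

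Groups and replicate numbers were taken from the sample labels and matched to the table columns by name. The labels mark replicates with R or D and a number and do not say what either letter means, so p-values measure only the spread between these libraries, which may be technical. In the CD2 screen the numbers are 2 and 3. Library totals ranged from 275169 to 42253496 reads, and no 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 8.85 to 449.68), so each counted as 1 replicate.

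Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), separately in each screen, by the quasi-likelihood F-test of the high against the low bin. TMM normalization was used, features with at least 10 counts in as many libraries as the smaller bin holds were kept, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 fold change is the log2 of the abundance in the high bin over that in the low bin. It is given with a standard error (SE) derived from the test, as its absolute value divided by the square root of the F statistic. For gene effects the counts of all gRNAs of a gene were summed and tested with the normalization of the gRNA table. In 3 joint models an interaction term compared the effects of a pair of screens with the same library: the 2 IL2RA activators, the CRISPRa and CRISPRi screens for CCR7, and the knockout screens with and without BATF3. Abundances are given as the mean CPM over the libraries of a bin, with the standard deviation (SD) over replicates. CPM are read counts scaled to a common library size, as edgeR defines them. Lists of transcription factors and chromatin genes, 15 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01 where at least 3 members were measured, with an estimated correlation as an alternative.

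Spacers were matched exactly to hg38 with the PAM of the enzyme on either strand, and tiling gRNAs were placed against the start of the canonical transcript in GENCODE v44. A distance is that from the middle of the spacer, negative upstream. Called gRNAs within 500 bp of the start site were compared with the others by a two-sided Fisher's exact test. This test treats gRNAs as independent, although spacers of a tile can overlap and gRNAs are not replicates. In the knockout library 144 of 6450 targeting gRNAs had over 1 site; the 94 non-targeting controls of the IL2RA library carry no sequence and were not matched.

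The genes and gRNAs named in the text follow a rule also fixed before the data were examined. In tiling screens these are up to 8 gRNAs per direction with the largest change past the threshold and the same sign at every replicate number. In the other screens they are the sorted protein's gene, BATF3, and up to 12 genes per direction by the same criterion, with up to 5 gRNAs where fewer than 5 genes passed. In interactions they are up to 8 per direction, and up to 4 members of a list may be named as examples, by smallest p. Every call met the same-sign criterion, which a passed test nearly implies, so that it is no separate support. CCR7 itself is not among the genes of the CCR7 libraries.

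Alternatives fixed at the same time were DESeq2 1.42.0, normalization by library size or by the non-targeting gRNAs, no count filter, at least 100 counts in every library, the replicate number as a block, leaving out each library in turn, camera over the gRNAs of a gene, a minimum of 2 gRNAs past the threshold, and windows of 250 and 1000 bp. After seeing the data, the removal of each library's GC trend (lowess, span 0.3), the crossed block for CD2 and non-targeting normalization of the joint models were added. Where leaving out a library left 1 in a bin, that library was assumed to vary like those of the other bin. Permutation tests used 100000 draws and bootstrap intervals 2000, or 500 for the comparison within 10 bins of abundance. Figures and site matching used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

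Each fit was also tested on counts simulated with known changes. Gene changes of 1 on the log2 scale were recovered in 100% of cases for the knockout screen without BATF3, 96% with BATF3, 92% for their difference and 100% for both CCR7 screens. For single gRNAs at the same size, recovery was 100% for CD2 and 70% for B2M, while the CRISPRa CCR7 screen recovered 17%, rising to 85% for a change of 2. In the simulated CCR7 difference, 3 unchanged genes passed, 13% of the calls. Simulated spread followed abundance alone, without extra spread of single gRNAs, and no shift between the bins was simulated. All gRNAs of a changed gene were given the same change, while several real gene calls rested on few gRNAs. Recovery in the real data may therefore be lower. The called genes of the CRISPRi CCR7 screen lay between −0.76 and 0.56, below the simulated size of 1, and recovery at such sizes was not measured.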

Results

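Sorting screens were run in primary human CD8 T cells and in Jurkat cells, an immortalized human T cell line. A library of gRNAs was delivered by lentivirus, cells were sorted into a low and a high bin of 1 surface protein, and the gRNAs of each bin were counted. The CD8 T cells had also been activated with beads against CD3 and CD28. Libraries tiling CD2 (2 replicates per bin, 828952 to 1189434 reads per library) and B2M (3 per bin, 275169 to 925453 reads) were screened with dSaCas9-KRAB in CD8 T cells. A library tiling IL2RA was screened in Jurkat cells with dSaCas9-VP64 (3 per bin, 429402 to 1481800 reads) and with VP64-dSaCas9-VP64 (3 per bin, 291762 to 1012964 reads). A library against 120 genes was sorted on CCR7, a chemokine receptor of naive and memory T cells, with CRISPRi (2 per bin, 487106 to 3065531 reads) and CRISPRa (3 per bin, 496292 to 2315248 reads). A knockout library against 1613 genes was sorted on IL7R, the interleukin-7 receptor, without BATF3 (2 per bin, 36035440 to 42253496 reads) and with BATF3 overexpressed (2 per bin, 26099730 to 35778055 reads). The labels of the screen with BATF3 add an electroporation step, so that BATF3 and this label changed together. Non-targeting gRNAs served as the background, and 0 of them passed the edgeR test in any of the 8 screens. At an unadjusted p under 0.05 they passed at 1.06% to 9.17% in 7 screens and at 23.09% in the knockout screen with BATF3.

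The first tiling screen addressed which positions around the start of CD2, a T cell adhesion molecule, lower its surface level when bound by dSaCas9-KRAB. The 141 targeting gRNAs covered positions 116754042 to 116755075 of chromosome 1 (hg38), at distances of −378 to 635 bp from the start site at 116754430. Of these, 16 were depleted from the CD2-high bin by more than any of the 250 non-targeting gRNAs, whose lowest log2 fold change was −0.43. All 16 were lower at both replicate numbers, and 15 lay within 500 bp of the start site, as did 118 of the 141 targeting gRNAs. Above the highest non-targeting gRNA (0.42) lay 1 targeting gRNA, CD2_131 (0.55), named here after its values were seen. The SD of the log2 fold changes was 0.41 over targeting and 0.152 over non-targeting gRNAs. No single gRNA passed: edgeR called 0 of 391 gRNAs at an adjusted p under 0.05, with 25 at an unadjusted p under 0.05. DESeq2 called 14 gRNAs, all lower. With library-size scaling edgeR also called gRNAs, as given in the part on processing. It did so with the crossed block as well, which pairs libraries of unlike numbers. That block was chosen after the data were seen and is no separate support. The gRNA CD2_73, chosen after its values were seen, had the smallest p (log2 fold change −1.38 ± 0.21, SE, n = 2 per bin, edgeR adjusted p = 0.171).

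The same design on B2M, the invariant light chain of MHC class I, gave 5 depleted gRNAs among 467 tested and 0 enriched. The library's 217 targeting gRNAs covered positions 44711109 to 44712177 of chromosome 15, where the transcript on the plus strand starts at 44711517. The largest depletion was that of B2M_29 (GGAGAGGAAGGACCAGAGCGG, 44711633 to 44711653, minus strand), 126 bp into the transcript in intron 1. It fell by 4.25 ± 0.61 on the log2 scale (SE, n = 3 per bin, adjusted p = 0.00189), from 15933 ± 7439 CPM (SD) in the low bin to 839.4 ± 354.0 in the high bin. B2M_2 (CACGGAGCGAGACATCTCGGC, 44711541 to 44711561, minus strand) lies in the coding part of exon 1 and changed by −3.73 ± 0.38 (adjusted p = 0.000267). B2M_3 (GAGCACAGCTAAGGCCACGGA, 44711556 to 44711576, minus strand), next to it in the same exon, changed by −3.12 ± 0.44 (adjusted p = 0.00177). B2M_150 (ACCTTTGGCCTACGGCGACGG, 44711849 to 44711869, plus strand) lies in intron 1 and changed by −3.12 ± 0.42 (adjusted p = 0.0015). B2M_84 (AGAAGGCATGCACTAGACTGG, 44711332 to 44711352, minus strand) lies 175 bp upstream of the transcript and changed by −2.12 ± 0.26 (adjusted p = 0.00101). All 5 were lower at all 3 replicate numbers. They lay within 500 bp of the start site, as did 186 of the 212 gRNAs that did not pass (Fisher's exact p = 1). DESeq2 called 12 gRNAs, 4 of them non-targeting.

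In Jurkat cells, 306 gRNAs were tiled at distances of −3956 to 962 bp from the start of IL2RA, the interleukin-2 receptor alpha chain (chromosome 10, 6061395 to 6066333, start site at 6062367 on the minus strand). With dSaCas9-VP64, in which 1 activation domain is fused to the dead Cas9, 7 gRNAs were enriched in the IL2RA-high bin and 0 depleted, all with the same sign at 3 replicate numbers. IL2RA_gRNA102 (TCAATTGCTGGAGGTGTGGGC, 6062480 to 6062500, plus strand), 123 bp upstream, rose by 6.44 ± 0.40 (SE, n = 3 per bin, adjusted p = 1.82e-11). Its CPM was 28879 ± 2726 (SD) in the high and 328.8 ± 108.3 in the low bin. IL2RA_gRNA43 (TAGATGGTTCCAAGAAGGGAG, 6061981 to 6062001, minus strand), 376 bp downstream in intron 1, rose by 5.11 ± 0.27 (adjusted p = 2.08e-12). IL2RA_gRNA84 (ATAGAGACTGGATGGACCCAC, 6062291 to 6062311, minus strand), in the 5′ untranslated part of exon 1, rose by 4.89 ± 0.31. IL2RA_gRNA119 (TCTCACCCAGCACTTCATAAG, 6062621 to 6062641, plus strand), 264 bp upstream, rose by 2.77 ± 0.25. The other 3 were IL2RA_gRNA120 at 1.37 ± 0.18, IL2RA_gRNA114 at 0.82 ± 0.17 and IL2RA_gRNA65 at 0.68 ± 0.18, the last with an adjusted p of 0.0497. IL2RA_gRNA65 did not pass with library size (0.255) or non-targeting normalization (0.0625), nor without low replicates 1 (0.154) and 2 (0.0797) or high replicates 1 (0.122), 2 (0.49) and 3 (0.0924), adjusted p-values in parentheses, and IL2RA_gRNA114 did not pass without high replicate 2 (0.209). All 7 lay within 500 bp of the start site, against 110 of the 299 gRNAs that did not pass (Fisher's exact p = 0.00107). In a window of 250 bp they were 4 of 7.

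With VP64-dSaCas9-VP64, which adds an activation domain at the other end of the protein, 8 gRNAs were enriched and 0 depleted. IL2RA_gRNA102 rose by 6.53 ± 0.38 (SE, n = 3 per bin, adjusted p = 1.97e-14), IL2RA_gRNA119 by 5.66 ± 0.35, IL2RA_gRNA84 by 5.55 ± 0.35 and IL2RA_gRNA43 by 4.26 ± 0.27. IL2RA_gRNA114 (AGATTCCCCTGCCGTTGAAGG, 6062571 to 6062591, plus strand) rose by 3.64 ± 0.29 and IL2RA_gRNA120 (ACTCAGCTTATGAAGTGCTGG, 6062627 to 6062647, minus strand) by 2.77 ± 0.24. IL2RA_gRNA118 (GTGCTGGGTGAGACCACTGCC, 6062613 to 6062633, minus strand) rose by 1.60 ± 0.23 and IL2RA_gRNA104 by 1.00 ± 0.21. All 8 lay within 500 bp, against 109 of 298 others (Fisher's exact p = 0.000392), and 4 of 8 within 250 bp. The start-site tests of both IL2RA screens use 1 library, and some called gRNAs overlap, so they are not independent support. The joint test of both screens found 4 gRNAs with a larger effect under VP64-dSaCas9-VP64 and 0 with a smaller one. These were IL2RA_gRNA119 (difference 2.91 ± 0.39, adjusted p = 1.92e-06), IL2RA_gRNA114 (2.83 ± 0.32, adjusted p = 4.63e-08), IL2RA_gRNA120 (1.41 ± 0.28, adjusted p = 0.0018) and IL2RA_gRNA118 (1.35 ± 0.27, adjusted p = 0.0018). They lie between 214 and 270 bp upstream of the start site. IL2RA_gRNA118 had a log2 fold change of 0.27 ± 0.17 under dSaCas9-VP64, which did not pass.

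**Figure D1:**
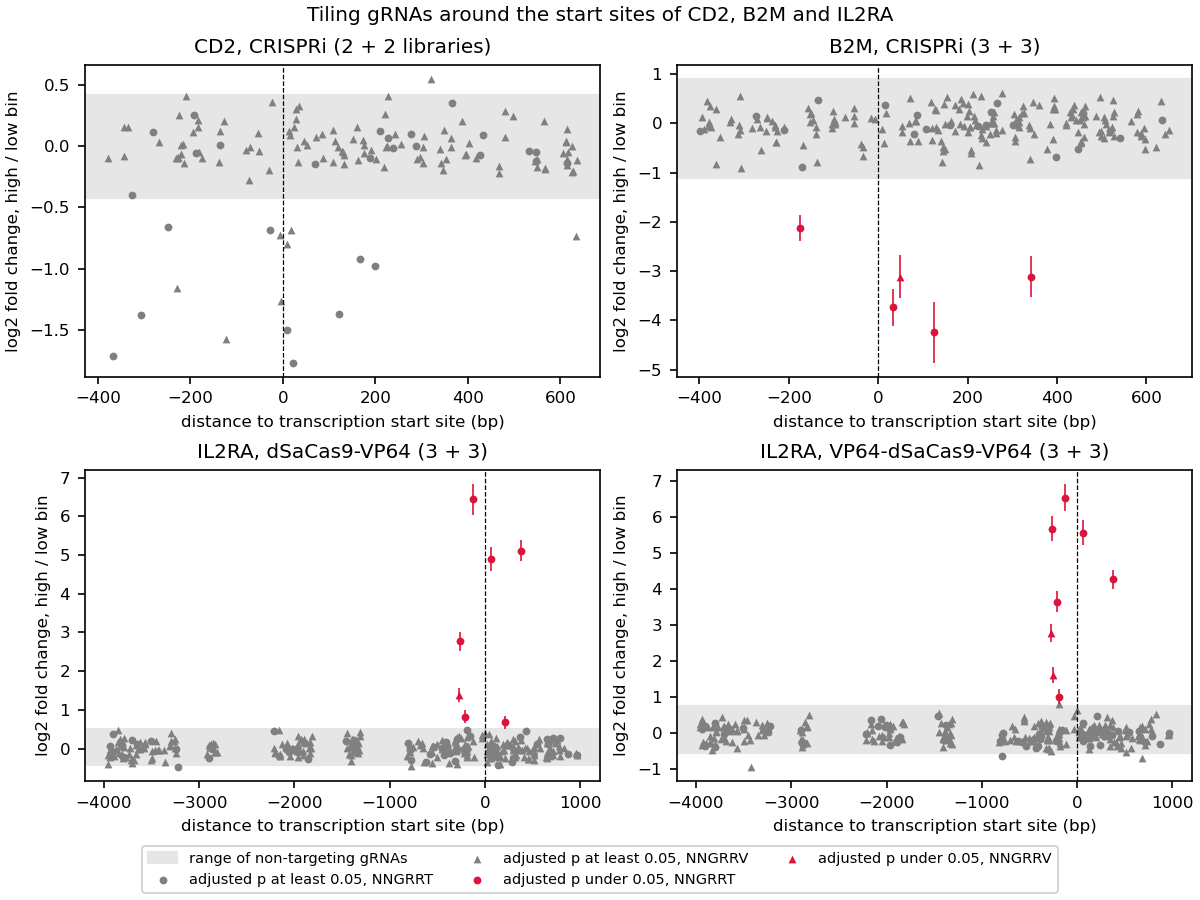
Log2 fold change of each tiling gRNA, high over low bin, against its distance to the start site in bp, with the range of the non-targeting gRNAs in grey and SE bars on gRNAs past an adjusted p of 0.05 (red). All red points lie within 500 bp of the start site: 5 lower for B2M, 7 higher for IL2RA with dSaCas9-VP64 and 8 with VP64-dSaCas9-VP64, while CD2 has 16 points below and 1 above the grey range and 0 red points.

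The CRISPRi screen on CCR7 asked which transcription factors and chromatin genes move CCR7 when repressed. At the gene level 8 of 120 genes passed, 5 with gRNAs enriched and 3 with gRNAs depleted in the CCR7-high bin, each with the same sign at both replicate numbers. The largest rise was that of STAT5A, a signal transducer of interleukin-2 and interleukin-7 receptors, at 0.56 ± 0.10 (SE, n = 2 per bin, adjusted p = 0.00115), with 15 of 16 gRNAs above 0. GATA3, a helper T cell regulator, rose by 0.32 ± 0.09 (adjusted p = 0.0349). In the BATF and AP-1 family, 3 of 8 measured members rose and 0 fell: BATF by 0.36 ± 0.09 (adjusted p = 0.0179), JUNB by 0.32 ± 0.07 (adjusted p = 0.00922) and BATF3 by 0.28 ± 0.08 (adjusted p = 0.0325). Adjusted over the list alone, the count was also 3. DNMT1, the maintenance DNA methyltransferase, changed by −0.76 ± 0.08 (adjusted p = 2.42e-07), MYB by −0.44 ± 0.11 (adjusted p = 0.0165) and TCF12 by −0.31 ± 0.08 (adjusted p = 0.019). Of their gRNAs, 14 of 16 for BATF, 17 of 23 for JUNB, 11 of 15 for GATA3 and 11 of 18 for BATF3 lay above 0, and 6 of 11 for MYB and 20 of 25 for TCF12 below. The median gRNA lay at −0.19 for DNMT1 and −0.16 for MYB, so that these gene values rested on few gRNAs. Groups of 16 non-targeting gRNAs reached the largest p-value of the called genes in 1 of 7 cases (14.29%, exact 95% interval 0.361 to 57.9), against 6.67% of genes, and an unadjusted p under 0.05 in 42.9%, against 11.7% of genes. Among single gRNAs, 0 rose and 2 fell of 2098 tested. DNMT1_1 (CTAGCCACCAGGGAGCTACGG, chromosome 19, 10194586 to 10194606, plus strand, intron 1) changed by −4.15 ± 0.41 (adjusted p = 0.0047), while 12 of the 18 DNMT1 gRNAs lay below 0. FOXO1_2 (GAAACTGGGAGGAAGGCGCGG, chromosome 13, 40666345 to 40666365, plus strand, untranslated part of exon 1) changed by −1.95 ± 0.27 (adjusted p = 0.0483). FOXO1, a factor of quiescent T cells, did not pass at the gene level by edgeR (−0.28 ± 0.14, adjusted p = 0.387). Of its 9 gRNAs 4 lay above 0, and the median gRNA lay at −0.06. By camera, 0 of 11 lists passed, with 3 at an unadjusted p under 0.05; the smallest adjusted p was 0.0651, that of the BATF and AP-1 family, whose test and mean (0.076) pointed up and whose median was −0.01. With an estimated correlation 0 passed as well, and 1 list, that family, passed without high replicate 2. The gene count rested on few libraries. It was 39 without low replicate 2, 12 without low replicate 1 and 1 without either high library, and the gRNA count was 832, 128 and 1 without low replicates 2 and 1 and high replicate 1. The gene count was 1 with normalization on the non-targeting gRNAs, and 5 with at least 100 counts in every library. With the replicate number as a block it was 1, that of DNMT1, and 0 gRNAs passed, so every other gene call ended. These blocked counts apply if a number marks a shared source, which the labels do not say.

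In the CRISPRa screen on CCR7, activation of 6 genes was followed by depletion from the CCR7-high bin, and 0 genes rose. BATF fell by 1.28 ± 0.29 (SE, n = 3 per bin, adjusted p = 0.0228; −0.73 without low replicate 1), EOMES, a T-box factor of memory cells, by 0.73 ± 0.16 (adjusted p = 0.0228) and FLI1, of the ETS family, by 0.68 ± 0.15 (adjusted p = 0.0228). BATF3 changed by −0.88 ± 0.14 (adjusted p = 0.00491) and STAT5B by −0.68 ± 0.11 (adjusted p = 0.00491), the latter with 13 of 15 gRNAs below 0. NFKB2 changed by −0.59 ± 0.14 (adjusted p = 0.0251). All 6 were lower at all 3 replicate numbers. The BATF, BATF3 and EOMES calls rested on fewer gRNAs, with 10 of 16, 11 of 18 and 7 of 13 below 0 and a median gRNA at −0.14, −0.16 and −0.01, while 11 of 13 lay below 0 for FLI1 and 14 of 20 for NFKB2. In the BATF and AP-1 family 2 of 8 members fell, or 3 adjusted over the list alone, and in the RUNX and ETS family 1 of 5, or 2 adjusted over the list alone. The median gene lay at −0.174, and library-size scaling moved it to 0.029, with 1 gene higher and 5 lower. Groups of 16 non-targeting gRNAs had a median of −0.256, so the background was itself shifted down. Of these groups, 0 of 7 reached the largest p-value of the called genes (upper bound 41%), against 5% of genes. At an unadjusted p under 0.05 the shares were 14.3% and 26.7%. The low bin was more uneven than the high bin, with an SD of non-targeting log2 CPM of 0.764 to 1.148 against 0.505 to 0.55. No single gRNA passed in edgeR (0 of 2099, with 182 at an unadjusted p under 0.05 and 34 called by DESeq2), and 2 did without low replicate 2. By camera 0 of 11 lists passed, with 0 at an unadjusted p under 0.05. DESeq2 called 34 genes, all lower, and camera over the gRNAs of each gene called 0. The edgeR count was 17 without low replicate 1, 13 without low replicate 3, and 1, 0 and 2 without high replicates 1, 2 and 3.

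The joint test of the CCR7 screens asked whether activation and repression of a gene act differently. It called 1 of 120 genes, BATF3, with a difference of −1.18 ± 0.21 (activation minus repression, adjusted p = 0.00836). BATF3 gRNAs were depleted from the CCR7-high bin under activation and enriched under repression. At the gene level, 0 other genes passed in the joint test by edgeR, with 17 genes at an unadjusted p under 0.05 and 5 called by DESeq2. The BATF3 call ended with at least 100 counts in every library (−0.71, adjusted p = 0.0869) and without either low library of the CRISPRi screen, where the count was 0. The count was 9, 9 and 6 without low replicates 1, 2 and 3 of the CRISPRa screen.

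**Figure D2:**
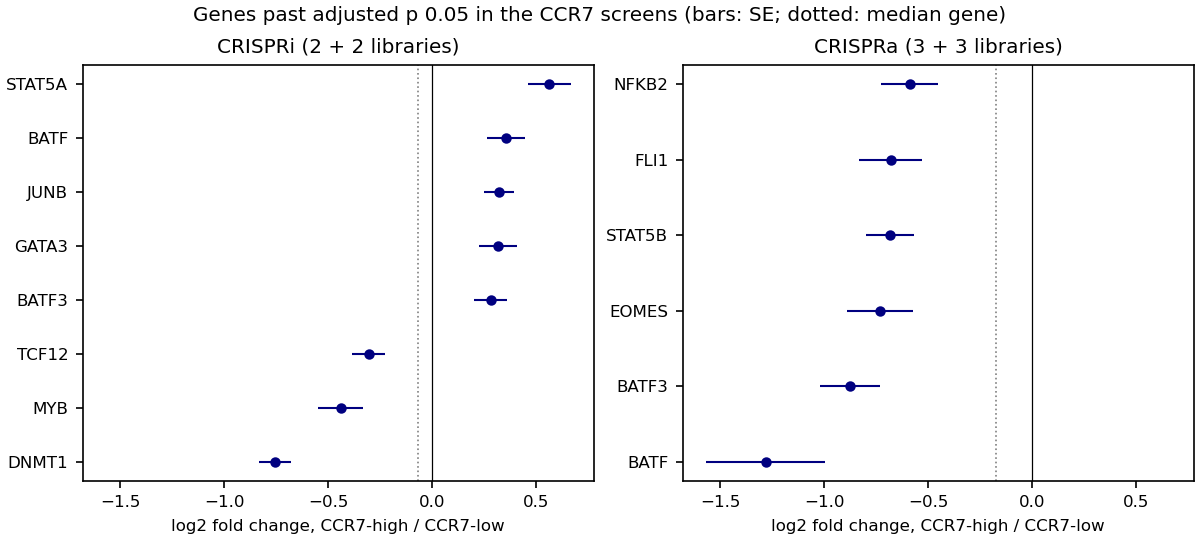
Genes past an adjusted p of 0.05 in the CCR7 screens, with the log2 fold change (CCR7-high over CCR7-low) on the horizontal axis, bars for the SE and a dotted line at the median gene. With CRISPRi 5 genes lie above and 3 below 0, with DNMT1 lowest at −0.76, and with CRISPRa all 6 genes lie below 0, with BATF lowest at −1.28, a size that rests on low replicate 1 (ratios of −2.07, −0.78 and −0.60 at the 3 replicate numbers).

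In the knockout screen without BATF3, gRNAs against IL7R itself were depleted from the IL7R-high bin, at −2.79 ± 0.18 (SE, n = 2 per bin, adjusted p = 6.49e-10), with 3 of 4 gRNAs past the threshold. Across 1613 genes, 18 rose and 15 fell, all 33 with the same sign at both replicate numbers. The largest rise was that of ZNF217, a zinc finger protein, at 2.15 ± 0.14 (adjusted p = 6.49e-10), followed by RUNX3, a CD8 lineage factor, at 1.42 ± 0.12 (adjusted p = 2.43e-08), with 4 of 4 gRNAs past the threshold. GATA3 rose by 1.35 ± 0.13 and FOXP1, a factor of T cell quiescence, by 1.28 ± 0.12. MYC, a driver of cell growth, rose by 1.03 ± 0.24 (adjusted p = 0.0178), ETS1 by 0.96 ± 0.17 and RBSN by 0.90 ± 0.12. GFI1 and the aryl hydrocarbon receptor AHR rose by 0.89 each (SE 0.18 and 0.12), and ARNT, the partner of AHR, by 0.78 ± 0.11. SON rose by 0.76 ± 0.15 and YBX1, with 1 of 4 gRNAs matching 2 sites, by 0.71 ± 0.15. Of the genes with depleted gRNAs, DNMT1 changed by −1.87 ± 0.17 (adjusted p = 1.43e-07) and FOXO1, an activator of the IL7R gene, by −1.75 ± 0.16 (adjusted p = 1.13e-07), with 4 of 4 gRNAs past the threshold. MBD2, which binds methylated DNA, changed by −1.39 ± 0.13, YY1 by −1.13 ± 0.15, the general transcription factor GTF2B by −1.12 ± 0.16 and the insulator protein CTCF by −0.95 ± 0.15. IRF1 changed by −0.86 ± 0.13, HIC1 by −0.70 ± 0.13, BHLHE40 by −0.55 ± 0.12, VEZF1 by −0.52 ± 0.12 and MBD6 by −0.50 ± 0.12. BATF3 stood at −0.02 ± 0.16 (adjusted p = 0.977), and its sign turned with the scaling. Groups of 4 non-targeting gRNAs reached the largest p-value of the called genes by edgeR in 0 of 137 cases (upper bound 2.66%, with 5.8% at an unadjusted p under 0.05), against 2.23% of genes (36, with 11.8% at an unadjusted p under 0.05) when both were tested together. Among 7000 single gRNAs, 25 rose and 24 fell; their count of 49 was 28 and 23 without high replicates 1 and 2. The count of 33 was 51 and 60 without low replicates 1 and 2 and 11 without either high library. DESeq2 called 67 genes, normalization on the non-targeting gRNAs 50 (33 higher, 17 lower), library size 28 (18 higher, 10 lower), and 14 genes had at least 2 gRNAs past the threshold.

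Grouped by list, 3 of 15 lists passed camera without BATF3, each upward with an adjusted p of 0.00203. These calls were lost with an estimated correlation. In the CD4 and helper list 3 of 10 members rose and 0 fell, namely GATA3, AHR and FOXP3 (0.60 ± 0.14), with a median of −0.004 and a mean of 0.24 over all members (adjusted p = 0.483 with an estimated correlation). Of the MYC, HIF and metabolic list, 2 of 13 members rose, ARNT and MYC, with a median of 0.112 (adjusted p = 0.483 with an estimated correlation). Of the RUNX and ETS family, 2 of 13 members rose, RUNX3 and ETS1, with a median of −0.042 and a mean of 0.212 (adjusted p = 0.568 with an estimated correlation). Adjusted over the list alone, the counts were 3, 3 and 5 higher, and 1 lower in the RUNX and ETS family. The T-box factor TBX21 (0.70 ± 0.14) and RUNX3 rose and HIC1 and BHLHE40 fell in the effector list of 8 measured members (adjusted p = 0.415). In the memory or naive list, FOXP1 and ETS1 rose and FOXO1 fell among 13 members (adjusted p = 0.971). DNMT1 fell in the list of DNA methylation and chromatin modifiers, of which 7 of 30 were in the library (adjusted p = 0.0741), and IRF1 fell among 9 interferon regulatory factors (adjusted p = 0.416). By edgeR over all genes, 0 members passed in the BATF and AP-1 family (12 measured), the exhaustion list (9), the NF-kB family (5), the Ikaros family (5), the STAT family (7), the KLF and SP family (16), the nuclear receptors (13) or the factors of other lineages (20). The smallest adjusted p of these lists by camera was 0.415. Adjusted over the list alone, NFKB2 was lower, STAT3 higher, KLF16 and KLF6 in opposite directions (1 higher, 1 lower), and 0 passed in the other 5 of these lists. Counted in that way, 3 members were higher and 3 lower in the effector list, 2 and 3 in the memory or naive list, 1 and 1 among the chromatin modifiers, and 0 and 1 among interferon regulatory factors.

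With BATF3 overexpressed, IL7R gRNAs were again depleted, at −2.24 ± 0.26 (SE, n = 2 per bin, adjusted p = 0.0102), and 8 genes rose and 17 fell. ZNF217 rose by 1.70 ± 0.20 (adjusted p = 0.0102), GATA3 by 1.48 ± 0.21, ARNT by 0.89 ± 0.15, RUNX3 by 0.88 ± 0.15 and FOXP1 by 0.84 ± 0.14. ZBTB32 rose by 0.86 ± 0.14, ZNF354B by 0.83 ± 0.15 and JRKL by 0.72 ± 0.13. FOXO1 fell by 2.33 ± 0.19 (adjusted p = 0.00343), BATF3 by 2.17 ± 0.39 (adjusted p = 0.0379), MYBL2, a cell cycle factor, by 1.86 ± 0.23, and DNMT1 by 1.86 ± 0.24. GTF2B fell by 1.79 ± 0.22, the transcriptional corepressor DRAP1 by 1.69 ± 0.21, MBD2 by 1.26 ± 0.13, HINFP by 1.23 ± 0.19 and HIC1 by 1.22 ± 0.20. ZNF626 (−2.19 ± 0.33) and FOXD4L3 (−1.76 ± 0.29) were also depleted, but all 4 of their gRNAs match more than 1 site, up to 36 sites for a ZNF626 gRNA and 5 for a FOXD4L3 gRNA. Groups of 4 non-targeting gRNAs reached the largest p-value of the called genes in 2 of 137 cases (1.46%, exact 95% interval 0.177 to 5.17), both upward, about as often as genes did (26, or 1.61%) when both were tested together. At an unadjusted p under 0.05 these shares were 42.3% and 25.7%. Among single gRNAs 2 passed. IL7R_3 (CCTGCAGAGAAAGCTCCAAC, chromosome 5, 35873512 to 35873531, plus strand, coding part of exon 5) fell by 3.62 ± 0.37 and ZNF217_1 (GGACACATAATGGCAAATCG, chromosome 20, 53582281 to 53582300, minus strand, coding part of exon 2) rose by 2.27 ± 0.25. The gRNA count was 11 and 12 without low replicates 1 and 2 and 2843 and 2194 without high replicates 1 and 2. By camera 0 of 15 lists passed, with 1 at an unadjusted p under 0.05 and 0 with an estimated correlation; 2 passed without high replicate 2. In this screen the median non-targeting gRNA lay at 0.257 and the median targeting gRNA at 0.005. The high bin was more uneven than the low bin, with an SD of non-targeting log2 CPM of 0.794 to 0.856 against 0.441 to 0.522. The chi-square per degree of freedom between its 2 libraries (449.68) was the highest of all pairs within a bin, a measure that also grows with depth. Normalization on the non-targeting gRNAs moved the median gene by −0.266 and gave 18 genes higher and 302 lower. Every gene named in this paragraph kept its sign under each scaling. All their effects were larger than such a shift, so this was no test of them. The count of 25 was 2 and 4 without low replicates 1 and 2, and 632 and 535 without high replicates 1 and 2. DESeq2 called 241 genes and library size 52 (11 higher, 41 lower), and 0 genes had at least 2 gRNAs past the threshold.

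**Figure D3:**
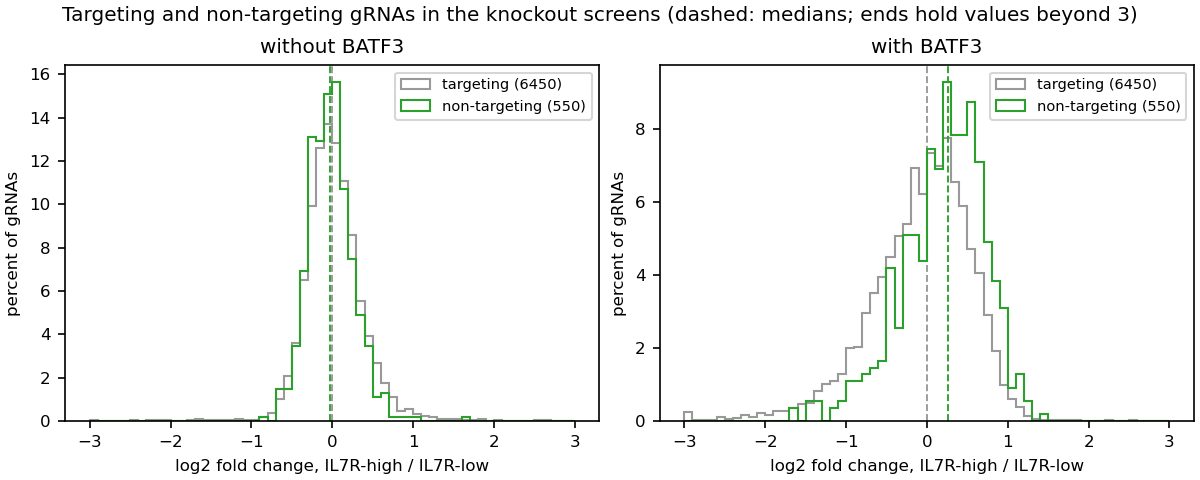
Distribution of gRNA log2 fold changes (IL7R-high over IL7R-low) in the knockout screens, as percent of the 6450 targeting and 550 non-targeting gRNAs, with dashed lines at the medians. Without BATF3 the medians lie at −0.003 and −0.031, and with BATF3 at 0.005 for targeting and 0.257 for non-targeting gRNAs.

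The called genes of the knockout screens overlapped in both directions. Higher in both were ARNT, FOXP1, GATA3, RUNX3 and ZNF217, 5 genes against 0.0893 expected for independent lists (one-sided Fisher's exact p = 5.2e-09). Lower in both were DNMT1, FOXO1, GTF2B, HIC1, IL7R and MBD2, 6 genes against 0.158 expected (one-sided Fisher's exact p = 2.42e-09). The screens share the gRNA library and no sequenced samples. Without low replicates 1 and 2 of the screen with BATF3 the overlap was 0 and 2 genes higher and 2 and 2 lower, without its high replicates 9 and 10 higher and 10 and 9 lower, and without single libraries of the other screen 4 to 5 higher and 4 to 6 lower. Over all 1613 genes the effects ranked in weakly opposite order (Spearman rho = −0.231, permutation p = 1e-05, the smallest that the draws allow, across genes, which are not independent replicates), while Pearson's r was 0.039 (p = 0.12) and −0.039 without the 2 farthest genes. Adjusted over 6 pairs of screens, the p-values were 6e-05 and 0.18.

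The joint test of the knockout screens asked which effects on IL7R depend on BATF3. It called 101 genes, 58 with a higher and 43 with a lower effect with BATF3. The effect of BATF3 knockout itself was lower by 2.15 ± 0.32 with BATF3 overexpressed (difference −2.15, SE 0.32, adjusted p = 0.0105). The MYC effect differed by −2.16 ± 0.37 (adjusted p = 0.0155), from 1.03 ± 0.24 without to −1.13 ± 0.31 with BATF3, the latter not past the threshold. MYBL2 differed by −2.43 ± 0.31 (adjusted p = 0.00473), TFDP1, a partner of E2F cell cycle factors, by −1.61 ± 0.42 (adjusted p = 0.0461) and DRAP1 by −1.57 ± 0.26 (adjusted p = 0.0148). STAT5B differed by −1.50 ± 0.33 (adjusted p = 0.0317), KLF11 by −0.91 ± 0.23, IRF4, a partner of BATF factors, by −0.90 ± 0.25 (adjusted p = 0.0496) and CEBPB by −0.81 ± 0.22. ZNF626 (−3.03 ± 0.43), FOXD4L3 (−2.32 ± 0.45) and DUX4 (−2.29 ± 0.42) had the other large negative differences, and all 4 gRNAs of each match more than 1 site. Higher with BATF3 were ZNF431 (1.16 ± 0.21, with 1 of 4 gRNAs matching 8 sites), ZBTB32 (1.02 ± 0.17), DMTF1 (0.96 ± 0.22), ZNF577 (0.93 ± 0.25, or 0.55 without high replicate 1 of the screen with BATF3), ZNF17 (0.93 ± 0.17), ZNF140 (0.88 ± 0.18), ZNF793 (0.88 ± 0.16) and JRKL (0.85 ± 0.17). In the KLF and SP family SP1 (0.74 ± 0.20) and KLF3 (0.67 ± 0.16) were higher and KLF11 lower among 16 members. The BATF and AP-1 family, interferon regulatory factors, STAT family, MYC list and other-lineage list had 1 lower member each, and the remaining lists had 0 past the edgeR threshold over all genes. Adjusted over the list alone, the effector and STAT lists had 1 higher and 1 lower member each, the MYC list 2 lower and the other-lineage list 4 lower. Groups of 4 non-targeting gRNAs reached the largest p-value of the called genes as often as or more often than genes did, at 10.95% (15 of 137, exact 95% interval 6.26 to 17.4) against 6.63%, when both were tested together. Of these, 14 were higher and 1 lower with BATF3. Removal of the GC trend gave 28 calls. Normalization on the non-targeting gRNAs moved the median difference by −0.298 and gave 4 genes higher and 171 lower. Library size gave 18 higher and 67 lower. The differences named here kept their sign under both. All of them were larger than such a shift, so this was no test of them. Without single libraries of the screen with BATF3 the count was 12, 2, 422 and 284 (low 1, low 2, high 1, high 2), and for the screen without BATF3 it was 1, 13, 1 and 3.

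**Figure D4:**
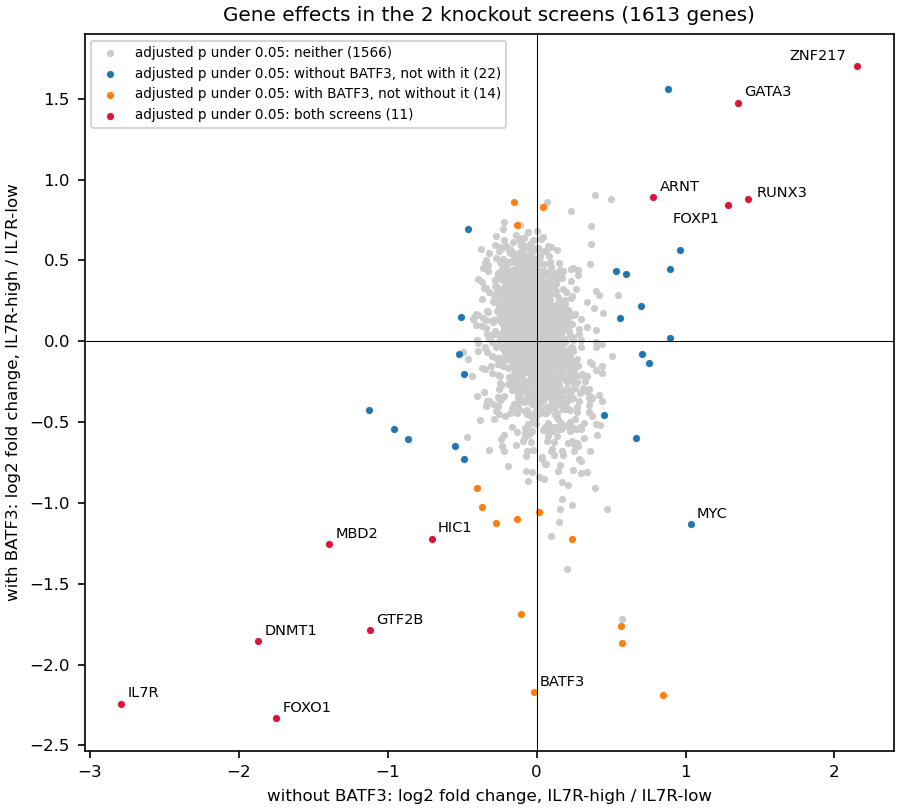
Gene log2 fold changes (IL7R-high over IL7R-low) without BATF3 on the horizontal and with BATF3 on the vertical axis, 1 point per gene, coloured by the screen in which the adjusted p was under 0.05. The 11 red genes passed in both screens with the same sign; BATF3 lies at −0.02 without and −2.17 with BATF3, and MYC at 1.03 and −1.13.

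For single gRNAs the joint test called 30 of 7000, 3 higher and 27 lower with BATF3, 2 of them non-targeting. The largest differences were those of NANOGNB_4 (−6.54 ± 0.91, adjusted p = 0.0182), NFYB_1 (−5.39 ± 0.97), HINFP_2 (−4.92 ± 0.88), DUX4_4 (−4.72 ± 0.70) and ZNF626_1 (−3.76 ± 0.65). A NANOGNB gRNA of the library matches 3881 sites of the genome. NFE2_2 (−3.68 ± 0.73), FOXJ1_1 (−3.63 ± 0.54) and ZNF506_3 (−3.58 ± 0.70) followed. Higher were the non-targeting gRNA NT_50 (1.80 ± 0.37), PITX3_2 (1.55 ± 0.30) and ZBTB32_4 (1.54 ± 0.31). The count was 1683 and 1216 without high replicates 1 and 2 of the screen with BATF3, and 0 by edgeR when any of the other 6 libraries was left out; 1522 gRNAs had an unadjusted p under 0.05 with all libraries, and DESeq2 called 577.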

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

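The counts of other splits, the sizes after removal of the GC trend, the PAM comparison within 500 bp and the share of non-targeting groups per direction were chosen after the results were seen. The other tests were chosen before the values they measure were seen.

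Differences between screens stand out here because a joint test of the 2 effects passed. For IL2RA, the 2 activators differed at 4 gRNAs, with a larger effect under VP64-dSaCas9-VP64: IL2RA_gRNA119 by 2.91, IL2RA_gRNA114 by 2.83, IL2RA_gRNA120 by 1.41 and IL2RA_gRNA118 by 1.35. Of 100 drawn splits of the libraries within each screen, 7 gave as many calls, with 5 as the highest other value against the real 4, but the other 6 of these splits kept all 6 libraries of the VP64-dSaCas9-VP64 screen in their bins and mixed those of the dSaCas9-VP64 screen alone. They keep the effect of the former screen, so this count does not answer whether chance gave the 4 differences. For CCR7, activation and repression differed at 1 gene, BATF3, by −1.18.

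The knockout screens with and without BATF3 differed at 101 genes. Higher with BATF3 were ZNF431 by 1.16, ZBTB32 by 1.02, DMTF1 by 0.96, ZNF577 by 0.93, ZNF17 by 0.93, ZNF140 by 0.88, ZNF793 by 0.88, JRKL by 0.85, SP1 by 0.74 and KLF3 by 0.67. Lower were ZNF626 (−3.03), MYBL2 (−2.43), FOXD4L3 (−2.32), DUX4 (−2.29), MYC (−2.16), BATF3 (−2.15), TFDP1 (−1.61), DRAP1 (−1.57), STAT5B (−1.50), KLF11 (−0.91), IRF4 (−0.90) and CEBPB (−0.81). At the gRNA level 30 differed, among them NT_50 (1.80), PITX3_2 (1.55), ZBTB32_4 (1.54), NANOGNB_4 (−6.54), NFYB_1 (−5.39), HINFP_2 (−4.92), DUX4_4 (−4.72), ZNF626_1 (−3.76), NFE2_2 (−3.68), FOXJ1_1 (−3.63) and ZNF506_3 (−3.58).

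For these gene differences, sizes were compared before and after each library's GC trend was removed. Those that remained had a median of 86% of those before (95% interval 83.1 to 91.3). This argues against the GC content of the spacers as the whole cause of the sizes. The called genes had been picked for large differences, however, so a partial effect of GC content stays open. Of the 101 calls, 26.7% (27) stayed past the threshold, as GC content would predict. All 101 kept their sign and 81 stayed under an adjusted p of 0.1, with a median size of 0.821 before and 0.734 after. The median SE was 0.195 and 0.194, so that calls near the threshold ended with a loss of this size. In the higher direction the median went from 0.74 to 0.585 and 12 of 58 calls stayed. In the lower direction it went from −1.033 to −0.973 and 15 of 43 stayed. Background between bins may account for calls in the higher direction, since groups of 4 non-targeting gRNAs reached the same p-value there in 10.22% of cases (5.7 to 16.6) against 3.78% of genes, and in both directions together in 10.95% (6.26 to 17.4) against 6.63%, a share inside that interval. In the lower direction the shares were 0.73% (upper bound 4) and 2.85%, and background and gene effects cannot be told apart with 137 groups. An effect of BATF3 itself stays open, as does the electroporation step that the labels give with BATF3 alone.

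In the screen with BATF3, non-targeting gRNAs lay above targeting gRNAs by a median of 0.252 (95% interval 0.205 to 0.3). The GC content of the spacers is argued against as the cause, since the difference was 0.296 (0.247 to 0.365) once the GC trend was removed. Abundance in the library stays open, with a mean difference of 0.168 (0.117 to 0.231) within 10 bins of abundance, between the values set for and against it. DNA cutting by targeting gRNAs stays open as well: gRNAs with over 1 genome site differed from those with 1 by 0.001 (−0.24 to 0.108, permutation p = 0.984), an interval that includes the loss that cutting would predict. Without BATF3, where the same library was used with a cutting Cas9, the medians were −0.031 for non-targeting and −0.003 for targeting gRNAs. These values argue against abundance or cutting that acts alike in both screens. Either of them acting with BATF3 alone stays open. A biological effect of knockouts on the sorted bins was not tested.

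Called tiling gRNAs were a small share of those near the start sites, and the base at the end of the PAM may set which of them act. Called gRNAs carried a T at the end of the PAM in 4 of 5 cases for B2M, against 9.9% of all other targeting gRNAs of the library, and in 7 of 9 cases for IL2RA, against 20.5%. The odds ratio over both libraries was 19.7 (95% interval 4.93 to 115, exact Mantel-Haenszel p = 8.11e-07), and 19.9 (4.86 to 118, p = 1.19e-06) among gRNAs within 500 bp of the start sites, where 9.7% and 20.4% of the others carried it. The 2 IL2RA screens share 1 library and were counted once, and no biological explanation was tested. The odds ratios treat gRNAs as independent, which overlapping spacers are not.

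With 3 libraries per bin there are 10 splits, too few for a share under 0.05. The real count was 5 for B2M (highest other split 0, 1 split with as many), 7 for IL2RA with dSaCas9-VP64 (highest other 0, 1 split) and 8 with VP64-dSaCas9-VP64 (highest other 1, 1 split). In the CRISPRa screen on CCR7 it was 6 genes (highest other 0, 1 split), 0 gRNAs in edgeR (highest other 0, 10 splits; 182 at an unadjusted p under 0.05, 34 by DESeq2) and 0 lists by camera (highest other 1, 10 splits; 0 at an unadjusted p under 0.05).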

How the results depend on the processing

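The removal of the GC trend, alone or with the replicate block, the crossed block for CD2 and the non-targeting normalization of the knockout difference were chosen after the data were seen.

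The 4 IL2RA differences and the 5 B2M calls kept their number in every alternative run except DESeq2 for B2M (12). The IL2RA counts stayed within 1.5 times throughout, at 5 to 7 and 8 to 9 without single libraries. Of the values for single genes and gRNAs under the alternatives fixed at the start, 1066 kept sign and call, 321 kept the sign and lost the call, and 4 changed sign; under those added later 140 kept both and 31 lost the call. All 4 were BATF3 in the knockout screen without BATF3, at 0.012 with library size, 0.013 with non-targeting normalization, 0.0047 without low replicate 2 and 0.068 without high replicate 2, none past the threshold. The cause was not tested for any change below unless given.

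With DESeq2 the counts were 14 gRNAs for CD2, 22 for CRISPRi CCR7, 34 gRNAs and 34 genes for CRISPRa CCR7, 87 gRNAs and 67 genes for the knockout without BATF3, 504 (54 non-targeting) and 241 with BATF3, 577 and 250 for their difference, and 5 for the CCR7 difference. Near the start site its calls were 13 for CD2 and 8 for B2M. With library size alone they were 8 for CD2, 1 gRNA for CRISPRi CCR7, 9 gRNAs and 52 genes for the knockout with BATF3, 72 gRNAs for its difference and 3 for the CCR7 difference. This scaling moved the median log2 value by 0.104 for B2M, −0.115 and −0.166 for the IL2RA screens, 0.161 for the CCR7 difference and −0.117 for the knockout difference. With normalization on the non-targeting gRNAs they were 1 gRNA and 1 gene for CRISPRi CCR7, 50 genes without BATF3, 69 gRNAs and 320 genes with it, and 195 and 175 for the difference, of which 47 genes were shared; 1 non-targeting gRNA passed over the 8 screens.

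At least 100 counts in every library gave 1 gRNA and 5 genes for CRISPRi CCR7 and 6 gRNAs for the knockout with BATF3. The replicate block gave 0 gRNAs and 1 gene (DNMT1) for CRISPRi CCR7, 1 gRNA for CRISPRa CCR7, 6 for IL2RA with dSaCas9-VP64 (without IL2RA_gRNA65), 93 gRNAs without BATF3, 345 gRNAs and 213 genes with it, 90 gRNAs for the difference and 7 for the CCR7 difference. Over all gRNAs, in no screen with 3 numbers did the deviations of every same-numbered pair correlate above 0.1, although for IL2RA with dSaCas9-VP64 they did over the non-targeting gRNAs (0.166, 0.112 and 0.151; over all gRNAs 0.136, 0.076 and 0.128). Low libraries correlated best with the high library of their number in both IL2RA screens and CRISPRa CCR7, and not in B2M. The labels do not say whether a number marks a shared source; if it does, the blocked counts apply. For CD2 the correlation was −0.102 over all gRNAs and 0.134 over the non-targeting gRNAs. There the crossed block gave 16. It pairs each low library with the high library of the other number, against the labels, so that its count is no separate support. Removal of the GC trend gave 28 genes for the knockout difference, 27 of them shared, and 44 with the block, which with BATF3 gave 145. Asking for 2 gRNAs past the threshold gave 0 genes for both CCR7 screens, 14 without BATF3 and 0 with it, by construction at most the number of genes with 2 called gRNAs. Camera over gRNAs gave 0 genes for CRISPRa CCR7, and an estimated correlation 0 lists without BATF3. A window of 250 bp held 4 IL2RA calls in each screen.

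Without single libraries, counts ranged from 0 to 0 for CD2, 5 to 5 for B2M, 1 to 832 gRNAs and 1 to 39 genes for CRISPRi CCR7, and 0 to 2 and 0 to 17 for CRISPRa CCR7. They ranged from 23 to 63 gRNAs and 11 to 60 genes without BATF3, 11 to 2843 and 2 to 632 with it, 0 to 1683 and 1 to 422 for the difference, and 0 to 9 for the CCR7 difference. Lists ranged from 0 to 1 for CRISPRi CCR7, 3 to 4 without BATF3 and 0 to 2 with it. What depth limits was not tested by thinning the counts. Recovery of simulated gRNA changes of 1 did not follow the median count per gRNA, at 17% for CRISPRa CCR7 (204 to 1072), 51% for CRISPRi CCR7 (227 to 1437) and 23% for the knockout with BATF3 (3580 to 4588).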

Other observations

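The tests in this part were all chosen after the values were seen.

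Gene effects on CCR7 by CRISPRi and on IL7R by knockout without BATF3 may run in 1 direction. Over 114 shared genes Spearman's rho was 0.1 (permutation p = 0.29, adjusted 0.58 over 6 pairs of screens), which leaves this open. Pearson's r was 0.314 (permutation p = 0.0018, adjusted 0.011) and 0.175 without the 2 farthest genes, so that much of it rests on those. These values are across genes, which are not independent replicates.

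The opposite rank order of gene effects with and without BATF3 (rho −0.231) could come in part from the GC content of the spacers, since effects of targeting gRNAs rose with GC content without BATF3 (rho 0.124) and fell with it (rho −0.249). Once the GC trend was removed, rho was −0.189 (95% interval −0.235 to −0.141, which treats genes as independent). GC content as the whole cause would need a rho above −0.10. The value and its interval lay below that, which argues against GC content as the whole cause over these genes, taken as independent. The value did not reach the stricter limit that had been set against this cause. Whether GC content gave a part of the opposite order stays open.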
